A study of Mus musculus with 6 samples.

How the data were processed

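RNA sequencing of GFP and B220 positive leukaemia cells from mouse bone marrow gave 6 libraries, 3 WT and 3 KO, with 1.3 ug of total RNA per library per the labels. The genome build is GRCm38 (mm10) per the submitters' processing notes. The aligner and the counting program are not given in the sources used here. The deposited count table holds whole-number counts per Ensembl gene, with gene symbols, biotypes and positions given by the authors for 55487 genes, of which 29176 had 0 counts in all libraries. The deposited tables that the authors named for FPKM and for TPM both hold CPM (counts scaled to library totals of 1e6): all 332922 values of each equal the count divided by the library total and multiplied by 1e6, within a tolerance of 0.001, with no correction for gene length. The authors' comparison table holds a log2 fold change, a fold change as a ratio, and a p-value and an FDR per gene from DESeq2, per the file headers and a deposited statistics table. The version of DESeq2 that the authors used is not stated.

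Groups were the genotypes in the labels. The labels do not say whether a library number refers to a mouse, a donor or a batch, and name no batch. Library totals ran from 17704382 to 29237035 counts, and 3 counts, the floor used for a count of 0, corresponded to 0.103 to 0.169 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Intervals of shares are exact 95% Clopper-Pearson intervals, and ratios of group counts with 1 to 3 counts in a group carry 95% counting intervals.

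Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14481 genes. TMM factors ran from 0.932 to 1.05. Genes were tested with the edgeR quasi-likelihood F test on genotype alone, with Benjamini-Hochberg (BH) adjustment over the genes tested and a threshold of 0.05, and all adjusted p-values of single genes come from this fit unless another tool is named. The common biological coefficient of variation was 16.8%. The SE of a log2 fold change is its size divided by the square root of the F statistic. Pbx3 and Bcl2 were also tested with a two-sided exact permutation test.

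The choices of test, lists and alternatives were made before the data were examined, except those named as added. There were 38 lists of 517 different genes, covering pathways, sample quality and the cell types that the sort could let through. They were tested with camera at a preset correlation of 0.01, with BH adjustment over the lists, and again with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way. Members were counted by the adjustment over all genes tested and again over the list alone. Several genes stand in more than one list, such as Btg2, Atf3 and Bcl6.

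The genes named were fixed by a rule: Mir182, Mir96, Mir183, Pbx3, Bcl2 and the reported targets; the 12 largest rises and 12 largest falls with an adjusted p below 0.05, with no overlap between genotypes and a mean of at least 5 CPM in the higher group, leaving out immune receptor segments, sex-linked genes and provisional symbols; up to 4 members of each list with the smallest p; and the leading V segment of each library. Examples in the text come from these 4 members, and other genes are named as chosen after their values were seen. Some genes that the rule names are not reported here.

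Seed matches were searched in the longest annotated 3′ UTR of each gene, taken from GENCODE transcripts on GRCm38, and 82.6% of the tested genes had one. The match was the 7mer-m8 TTGCCAA, compared with 629 other orderings of the same 7 bases, with the 8mer TTGCCAAA and with the 7mer-A1 TGCCAAA as alternatives. Chromosomes were compared over genes with a mean of at least 8 CPM.

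The procedure was tested on simulated data with 200 changed genes, far fewer than in the real comparison, so that its adjusted threshold was stricter. At this number of libraries it recovered 0.1% of genes changed 1.5-fold, 60.7% of those changed 2-fold (8.58% of calls false) and 91.0% of those changed 4-fold (6.95% false). Camera found 10 of 10 shifted sets, with 0 false sets. The simulated genes were independent, while the interferon list, for example, had an estimated correlation of 0.913. False sets that arise from correlation between genes could therefore not show here. A shift of 0.2 log2 given to genes with a seed match, on independent noise in place of the data, was recovered as 0.202 (SD 0.040) over 20 draws, at a mean percentile of 98.3.

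Alternatives were other normalisations, tools, filters and units, leaving out classes of genes, the replicate number as a block, and leaving out each library in turn. The counts recovered from the CPM tables, the neutrophil marker level as a covariate, and leaving out chromosomes 12 and 19 were added after the data had been seen. They were run on every result, except that genes of chromosomes 12 and 19 have no value in the fit without them. The alternatives meant for FPKM and TPM ran on CPM, which is what those tables hold. Enrichment of GO or KEGG terms was not run, because the deposited tables carry no term annotation.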

Results

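Messenger RNA was sequenced from acute lymphoblastic leukaemia cells of mouse bone marrow, sorted as positive for GFP, which marks the transplanted cells, and for B220, a B-lineage surface protein. The 6 libraries fell into 2 groups of 3 by genotype: wild type (WT, replicates 1, 3 and 4) and knockout of the microRNA miR-182 (KO, replicates 2, 3 and 4). The series describes a B-lineage leukaemia driven by BCR-ABL and a T-lineage leukaemia driven by Notch, and every library here came from the B220 sort. Total counts were 17704382, 23311040 and 17883609 in WT replicates 1, 3 and 4, and 20527487, 26886480 and 29237035 in KO replicates 2, 3 and 4. At these totals 3 counts correspond to between 0.103 and 0.169 CPM (counts scaled to equal library totals of 1e6), and 14481 of the 55487 genes listed had enough counts to test. Levels below are TMM-normalised CPM, given as mean ± SD of 3 libraries, and fold changes are log2 KO over WT with their standard error (SE).

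The comparison asked what the loss of miR-182 changes in these cells, with Pbx3 and Bcl2 named in the series title as targets of the microRNA. Mir182 itself, on chromosome 6 from 30165918 to 30165992 (minus strand, GRCm38), had 0 counts in all 6 libraries, as had Mir96 and Mir183 of the same cluster. An mRNA library does not measure the mature microRNA, so the genotype could not be checked from these counts. Of the 5 tested protein-coding neighbours in the list fixed for this locus, Tmem209 (0.48, SE 0.06, adjusted p = 0.00134) and Zc3hc1 (0.32, SE 0.09, adjusted p = 0.0215) rose and Ube2h fell (-1.07, SE 0.18, adjusted p = 0.00306). Nrf1 and Klhdc10 did not pass, at 0.06 and -0.15, though Klhdc10 did in limma-voom with quality weights (adjusted p = 0.0108). The counts were the same when adjusted over the list alone, 2 up and 1 down. The call of Zc3hc1 was lost without WT replicate 4 (adjusted p = 0.0559), without KO replicate 3 (0.0675) and without KO replicate 4 (0.059), and over 23 alternatives its adjusted p ran from 0.00601 to 0.513. Each of these left-out libraries left 1 neighbour risen. The list as a whole was not called (camera adjusted p = 0.812), with a median of 0.06 and a mean of -0.07.

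Neither Pbx3 nor Bcl2 was higher in the KO libraries. Pbx3, a homeodomain transcription factor (ENSMUSG00000038718, chromosome 2 from 34171457 to 34373142, minus strand), was expressed at a low level, 1.57 ± 0.487 CPM in WT and 0.882 ± 0.185 CPM in KO. Its log2 fold change was -0.81 (SE 0.32, adjusted p = 0.0664), and the ranges of the groups overlapped. Bcl2, which protects cells from apoptosis (ENSMUSG00000057329, chromosome 1 from 106538178 to 106714274, minus strand), stood at 24.5 ± 3.72 CPM in WT and 22.2 ± 1.62 CPM in KO, a log2 fold change of -0.14 (SE 0.13, adjusted p = 0.387). Two-sided exact permutation tests gave p = 0.2 for Pbx3 and p = 0.5 for Bcl2, where 3 against 3 libraries cannot go below 0.1. Pbx3 passed as lower in KO without WT replicate 3 (-1.06, adjusted p = 0.0166) and in limma-voom with quality weights (-1.04, adjusted p = 0.00496), and stood at 0.06 (adjusted p = 0.974) with the libraries' neutrophil marker level as a covariate. Over the 23 alternatives its adjusted p ran from 0.00496 to 0.974, and that of Bcl2 from 0.222 to 0.957. The list of these 2 genes was not called (camera adjusted p = 0.762), and neither gene passed when adjusted over the list alone.

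Genes reported elsewhere as targets of miR-182 moved in both directions. Of 16 tested, 5 rose, 3 fell and 8 did not pass, with the same counts when adjusted over the list alone. Ccnd2, a D-type cyclin, rose by 2.73 (SE 0.47) from 52.4 ± 36.3 to 348 ± 75.4 CPM, and Bnip3, a mitophagy receptor, by 2.01 (SE 0.14) from 14 ± 2.62 to 56 ± 1.99 CPM. Mtss1 (0.65) and Clock (0.51) also rose. Adcy6, an adenylate cyclase, fell by 6.50 (SE 0.33) from 183 ± 67.6 to 2.00 ± 0.329 CPM, and Foxo3, a forkhead transcription factor, fell by 1.05 (SE 0.10) from 101 ± 11.8 to 48.9 ± 2.15 CPM. Foxo1 fell by 0.46, a call that was lost without WT replicate 4 (adjusted p = 0.0532), KO replicate 2 (0.0635) or KO replicate 3 (0.0617), with a range of 0.000396 to 0.923 over the alternatives. Besides Pbx3 and Bcl2, the genes that did not pass were Mitf (-0.70), Cyld (-0.29), Brca1 (0.38), Pdcd4 (0.53), Fbxw7 (0.09) and Rasa1 (-0.13). Of these, Mitf (0.0327), Cyld (0.015) and Pdcd4 (0.0134) passed without WT replicate 3, and Brca1 (0.0287) without KO replicate 3. Pdcd4 (0.00404) and Cyld (0.00946) also passed in limma-voom with quality weights, and Cyld (0.0423) without chromosomes 12 and 19. Over all alternatives the adjusted p reached 0.883 for Mitf, 0.951 for Cyld, 0.552 for Pdcd4 and 0.45 for Brca1. Among all 16, 6 rose and 6 fell without WT replicate 3. The sign of Fbxw7 turned without WT replicate 1, to -0.0023. Rgs17 had 0 counts in all 6 libraries. As a list they were not called (camera adjusted p = 0.762), and the median of -0.02 lay on the other side of 0 from camera's direction and turned to 0.04 with upper-quartile factors and 0.09 in limma-trend on log2 of CPM plus 1.

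**Figure D1:**
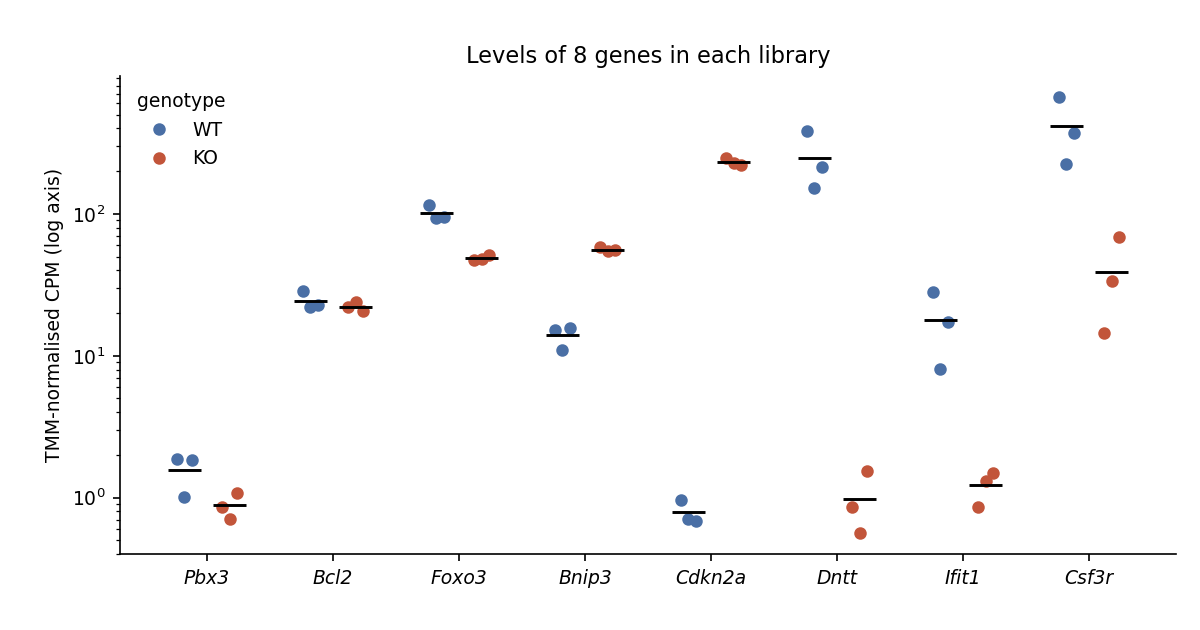
Levels of 8 genes in each of the 3 WT and 3 KO libraries, as TMM-normalised CPM on a log axis; points are libraries and bars are group means. The libraries of the 2 genotypes overlap for Pbx3 and Bcl2, while Cdkn2a stood at 0.787 CPM in WT and 231 CPM in KO.

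Genes carrying a seed match to miR-182-5p in the annotated 3′ UTR were not shifted upward in KO. Of 11966 tested genes with an annotated 3′ UTR, 1428 held a 7mer-m8 match (TTGCCAA), and their median log2 fold change was -0.09 against -0.01 for the others, a difference of -0.07 (camera p = 0.226, p = 0.283 with an estimated correlation). Among these 1428 genes 319 rose (22.3%) and 509 fell (35.6%), against 25.7% and 30.5% of the genes without a match. The other orderings of the same 7 bases, 629 in number, gave differences from -0.15 to 0.04, and the seed match ranked at percentile 15.1 among them. Genes with a match had longer 3′ UTRs, with a median of 2580.5 against 1026 bases. In limma's fry, which asks whether the genes move on balance one way without comparing them with others, the set passed as lower in KO. By this annotation the 3′ UTR of Bcl2 held 1 match and that of Pbx3 held 0.

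**Figure D2:**
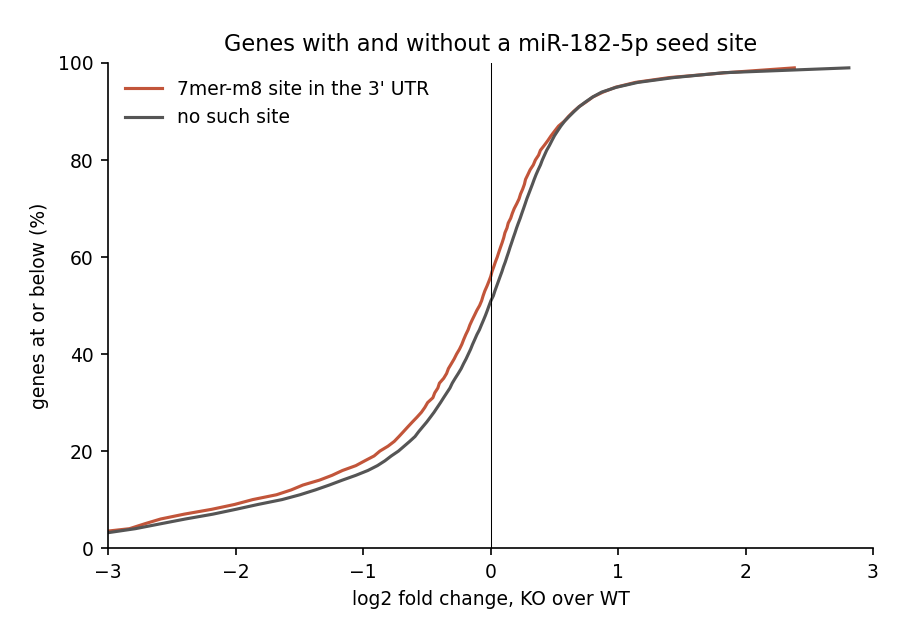
Cumulative share of tested genes, in percent, against log2 fold change KO over WT, for genes with and without a 7mer-m8 match in the 3′ UTR. The curve of the 1428 genes with a match lies slightly to the left, with a median of -0.09 against -0.01.

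The libraries of the 2 genotypes differed across a large part of the transcriptome. Libraries of a genotype held the same immunoglobulin heavy-chain V segments at high shares, as given below. A difference between genotypes could therefore not be told from one between leukaemias. In the edgeR quasi-likelihood fit 7599 of 14481 genes changed at an adjusted p below 0.05, 3466 higher and 4133 lower in KO, and 2915 of them by at least 2-fold, 797 higher and 2118 lower. All 3 libraries of one genotype lay above all 3 of the other in 64.0% of the tested genes, where chance gives 10%. The first principal component held 84.4% of the variance. With the mean log2 level of 17 neutrophil markers in each library as a covariate, of whose variance genotype itself took 82.1%, 485 genes passed, 187 higher and 298 lower, 482 of them shared with the 7599. Of 132 tested segments of immunoglobulin and T cell receptor genes, 34 rose and 18 fell.

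The largest differences upward in KO included the tumour suppressor locus on chromosome 4, where WT had almost no counts. A comparison of KO with WT cannot tell a rise in KO from a loss in WT. Cdkn2a, which encodes p16INK4a and p19ARF (chromosome 4 from 89274471 to 89294653, minus strand), rose by 8.20 (SE 0.14, adjusted p = 4.91e-07) from 0.787 ± 0.16 to 231 ± 13.1 CPM. Its neighbour Cdkn2b had 3 counts over the WT libraries and 416 over the KO libraries, a ratio of 98.5 with a counting interval of 33.5 to 480. Kcnma1, a potassium channel, rose by 8.65 from 0.315 ± 0.0751 to 130 ± 18.8 CPM, Zfp462 by 8.26, Bicc1 by 7.49, Rps6ka6 by 7.45, Trarg1 by 7.20, Col6a6 by 6.28, Ctxn3 by 6.25, Tead1 by 6.23 and Htra3 by 6.20. Frmpd1 had 2 counts over WT and 503 over KO, a ratio of 179 (49.2 to 1480). Among the falls, Slc17a8, a vesicular glutamate transporter, went from 105 ± 2.89 to 0.188 ± 0.122 CPM (-9.00), and Dntt, the terminal transferase of early lymphocytes, from 249 ± 120 to 0.987 ± 0.496 CPM (-7.94, SE 0.52). Sox6 (-8.91), Rxfp1 (-8.39), Ptpn14 (-8.32), Lrig3 (-7.64), Smoc1 (-7.39) and Abca9 (-7.30) also fell. Tmem100 had 862 counts over WT and 2 over KO, a ratio of 607 (167 to 5017), Meis2 had 1003 and 3, a ratio of 471 (161 to 2286), and Zfhx4 had 498 and 3, a ratio of 234 (79.5 to 1137). Aldh1a7 (-8.90, SE 1.33) did not pass in limma-voom (adjusted p = 0.0725, where the range over 22 alternatives was 2.14e-13 to 0.0725). Each gene of this paragraph passed with the neutrophil covariate.

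Of 38 gene lists fixed before the data were examined, 16 were called by camera, 3 higher and 13 lower in KO. None was called with an estimated correlation between genes, where 0 lists had an unadjusted p below 0.05 and the smallest was 0.0582, and fry called 19. Other splits of the 6 libraries into 3 and 3, each of which mixes the genotypes in both groups, called up to 20 lists. With the neutrophil marker level as a covariate, 10 of the 16 kept their call, 5 lost it and the neutrophil list turned to 0.10. Of the 150 genes named by rule that had passed, 44 kept their call with that covariate, 101 lost it and 5 turned direction. Of the 101, 27 had a fold change at least as large with the covariate and 37 one smaller by over 1.5 times, while the SE rose by a median factor of 2.37. Lost calls therefore do not show that the neutrophil level accounts for a gene's change. Adjusted p with an estimated correlation was 0.865 for each of the 16 except the DNA replication list.

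Myeloid, interferon and stress-response genes were lower in KO. All 17 neutrophil markers fell (median -2.95, camera adjusted p = 0.000784, adjusted p = 0.865 with an estimated correlation), among them Chil3 from 1382 ± 131 to 285 ± 160 CPM and Csf3r, the G-CSF receptor, from 419 ± 222 to 38.8 ± 27.5 CPM. Their summed level was 41228, 16900 and 29687 CPM in the WT libraries and 1397, 3304 and 7021 CPM in the KO libraries. Of 18 monocyte and macrophage markers 14 fell and 4 did not pass (median -1.85, adjusted p = 0.000784), with F13a1 at -1.95 (SE 0.22) and Cd14 at -2.32 (SE 0.30). All 24 interferon-stimulated genes fell (median -2.21, adjusted p = 1.01e-05), with Ifit1 at -3.83 (SE 0.49) and Oasl2 at -3.80 (SE 0.49). Of 17 immediate early and dissociation stress genes 14 fell, 15 when adjusted over the list alone, and 3 did not pass (median -1.52, adjusted p = 8.17e-05), with the heat shock gene Hspa1b at -2.19 (SE 0.13) and Hspa1a at -2.65 (SE 0.18). For each of these 3 lists adjusted p = 0.865 with an estimated correlation. With the neutrophil marker level as a covariate the monocyte list was not called (median -0.65, adjusted p = 0.0649) and the interferon list was (median -0.88, adjusted p = 0.0146). One interferon-stimulated gene that another list also holds, Bst2 (-0.57), lost its call without WT replicate 4 (adjusted p = 0.055), KO replicate 2 (0.124), KO replicate 3 (0.0668) or KO replicate 4 (0.106), with a range of 0.011 to 0.862 over the alternatives.

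Several markers of other blood lineages fell in the same KO libraries in which neutrophil markers were lower. Of 4 NK cell markers 3 fell (4 when adjusted over the list alone; median -2.19, adjusted p = 0.0169), with Klrb1c at -4.67 (49.3 ± 6.94 to 1.93 ± 0.661 CPM) and Gzmb at -2.40. Without WT replicate 3, 8 of 8 tested NK cell markers fell, but 2 of 5 without WT replicate 1 or WT replicate 4 and 2 of 8 without any one of the KO libraries. Of 13 T cell markers 8 fell, 1 rose and 4 did not pass (median -2.16, adjusted p = 0.0457), with Gata3 at -4.59 and Lck at -2.53, and the riser, named after its value was seen, was the adaptor Lat at 1.22. The number of T cell markers that fell was 15 of 18 tested without WT replicate 3, 4 without KO replicate 2, 3 without KO replicate 3 and 5 without KO replicate 4, and 0 rose without KO replicate 2 or KO replicate 3. All 5 mast cell and basophil markers fell (median -2.49, adjusted p = 0.0335), with Prss34 at -3.60 and Ms4a2 at -2.49. These 3 lists had adjusted p = 0.865 with an estimated correlation. Without KO replicate 4 the T cell and the mast cell lists were not called (adjusted p = 0.0542 each), nor were they with at least 1 CPM in 3 libraries (0.129 and 0.144), and fry did not call the T cell list (0.0518). With the neutrophil covariate none of the 3 was called (NK cells 0.121, T cells 0.122, mast cells 0.244). Their medians were then -0.0026, -0.94 and -1.26. Klrb1c at -4.69 (SE 0.62) and Lck at -3.93 (SE 0.62) kept their calls in that fit. Gata3 stood at -3.98 (SE 0.96) but did not pass (adjusted p = 0.0829). Gzmb moved to -0.45 (SE 1.37), Prss34 to -1.87 (SE 1.25) and Ms4a2 to -1.26 (SE 0.95), and none of them passed. Of 6 stem and progenitor markers 4 fell and 2 did not pass (list not called, adjusted p = 0.334), with Hlf at -1.86 and Mycn at -0.91. Only 2 of them fell without KO replicate 2 or KO replicate 3, and fry called the list as lower (adjusted p = 0.0341). Of 8 dendritic cell markers 2 fell, 1 when adjusted over the list alone, and 6 did not pass (adjusted p = 0.446), with Ly6d at -1.81. That count was 6 without WT replicate 3 and 1 without WT replicate 4 or any KO library. Of 6 stromal and endothelial markers 2 fell (3 fell and 1 rose when adjusted over the list alone) and 4 did not pass (adjusted p = 0.762), with Col1a1 at -2.08. A single stromal marker fell without WT replicate 1 or any KO library, with 1 risen without KO replicate 4, while 3 fell and 1 rose without WT replicate 3. Of 7 erythroid markers Car2 rose by 1.59 and 6 did not pass (adjusted p = 0.451), and without WT replicate 1 the list was called as higher, with 6 markers risen and a median of 1.42 (adjusted p = 0.00711, range over 14 alternatives 0.000722 to 0.875). Without WT replicate 3, 1 marker rose and 1 fell. The erythroid median of -0.04 and camera's direction differed in sign, and the median was 0.03 with upper-quartile factors and 0.54 in limma-trend on log2 of CPM plus 1. With the neutrophil covariate it was 1.12. The single megakaryocyte marker tested, Itga2b, did not pass (-0.86, adjusted p = 0.0648; passed when adjusted over the list alone, where it stands by itself, and passed without WT replicate 3 at 0.00801 and in limma-voom with quality weights at 0.00648; without KO replicate 2, 1 of 2 tested markers fell), and its list was not called (adjusted p = 0.762).

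MYC target genes were higher in KO. DNA replication genes were higher in KO replicates 2 and 4, with KO replicate 3 near the level of WT replicates 3 and 4. Of 22 MYC and ribosome biogenesis genes 19 rose, 20 when adjusted over the list alone, and 3 did not pass (median 0.57, camera adjusted p = 8.17e-05, adjusted p = 0.865 with an estimated correlation). Fbl, a nucleolar methyltransferase, rose from 176 ± 30.5 to 336 ± 7.24 CPM, and Pa2g4 from 231 ± 40.4 to 429 ± 15.8 CPM. Of 21 DNA replication genes 10 rose and 11 did not pass, and adjusted over the list alone 14 rose and 1 fell (median 0.42, adjusted p = 0.0184, adjusted p = 0.875 with an estimated correlation), with Rfc3 at 0.83 (SE 0.14) and Cdt1 at 0.62 (SE 0.14). The number risen was 6 without WT replicate 1, 5 without WT replicate 4, 4 without KO replicate 2, 17 without KO replicate 3, and 4 with 1 fallen without KO replicate 4. The mean log2 CPM of the DNA replication genes was 6.68, 6.94 and 6.93 in WT replicates 1, 3 and 4. In KO replicates 2, 3 and 4 it was 7.34, 6.95 and 7.42. The DNA replication list was not called without KO replicate 4 (adjusted p = 0.0546) or by fry (0.133). Of 18 homologous recombination and Fanconi genes 6 rose, 1 fell and 11 did not pass (adjusted p = 0.0953), with Fanca at 0.72 and Exo1 at 0.58. Without KO replicate 3 this list was called as higher (11 genes risen, median 0.52, adjusted p = 0.00292, range 0.00292 to 0.875), while 2 rose without WT replicate 4 or KO replicate 2 and 3 without KO replicate 4. The gene that fell was Rad52 (-0.79), a call lost without WT replicate 4 (adjusted p = 0.0529), KO replicate 2 (0.0586) or KO replicate 3 (0.06), with a range of 0.000681 to 0.947. Of 20 mitosis genes 1 rose, 0 when adjusted over the list alone (adjusted p = 0.446). It was Bub1b at 0.38, a call lost without WT replicate 1 (0.06), WT replicate 4 (0.0791) or KO replicate 4 (0.0571). Other mitosis genes passed in some of these fits: 2 rose without WT replicate 3 and 3 without KO replicate 3, and 1 fell without WT replicate 1 and 2 without KO replicate 4. The neutrophil marker level was lower in the same KO libraries, and with it as a covariate the mitosis list (adjusted p = 0.0364) and the recombination list (0.0185) were called as higher.

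**Figure D3:**
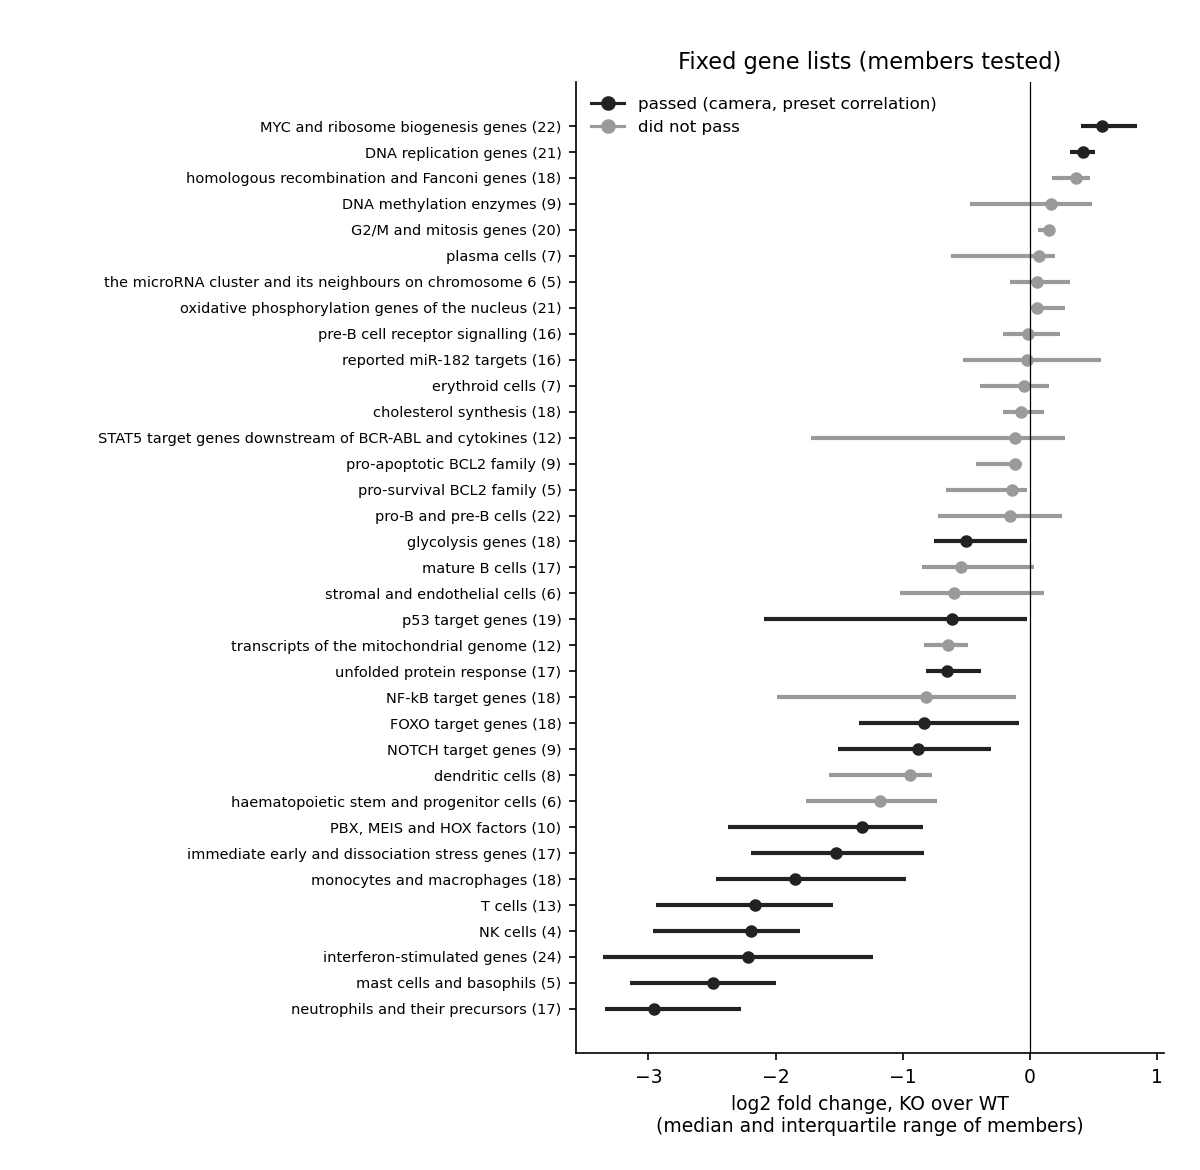
Median log2 fold change KO over WT (points) and interquartile range (lines) of the members of each fixed list with at least 4 tested genes, without the sex-linked list; numbers in brackets are genes tested, and black marks lists that camera called with its preset correlation. Medians run from -2.95 for neutrophil markers to 0.57 for MYC and ribosome biogenesis genes, and 0 lists were called with an estimated correlation.

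PBX, MEIS and HOX transcription factors were lower in KO as a group, with 7 of 10 fallen, 8 when adjusted over the list alone, and 3 not passed (median -1.32, camera adjusted p = 0.000784, adjusted p = 0.865 with an estimated correlation). Meis3 fell by 2.51, Hoxb4 by 1.26 and Pbx2 by 0.92, from 84.1 ± 18.1 to 44.5 ± 2.7 CPM. Of 19 p53 target genes 11 fell, 1 rose and 7 did not pass (median -0.61, adjusted p = 0.0104), with Cdkn1a, an inhibitor of cyclin-dependent kinases, at -2.72 (40.8 ± 7.41 to 6.17 ± 0.639 CPM) and Zmat3 at -2.42, and without WT replicate 1, 2 rose. Of 18 FOXO target genes 11 fell, 1 rose and 6 did not pass (median -0.83, adjusted p = 0.0179), with Sesn3 at -0.75. Of 18 glycolysis genes 9 fell, 1 rose and 8 did not pass (median -0.50, adjusted p = 0.0192), with Pfkp at -1.83 and Hk1 at -1.23. The number of glycolysis genes risen was 0 without WT replicate 1, WT replicate 4, KO replicate 2 or KO replicate 4, and 2 without WT replicate 3. Of 17 unfolded protein response genes 12 fell, 13 when adjusted over the list alone, and 1 rose (median -0.65, adjusted p = 0.0194), with Edem1 at -0.82 and Chac1 at -1.84. Of 9 NOTCH target genes 5 fell, 1 rose and 3 did not pass (median -0.88, adjusted p = 0.0451), with Notch3 at -3.93 (49.5 ± 15.9 to 3.25 ± 0.594 CPM) and Nrarp at -1.29. The risers, named after their values were seen, were Aen (0.60), Il7r (0.69), Pfkl (0.31), Asns (0.48) and Heyl (1.78), in the order of the lists. For each of these lists adjusted p = 0.865 with an estimated correlation. The unfolded protein response list was not called without WT replicate 3 (adjusted p = 0.0624) or KO replicate 4 (0.067), and the NOTCH list not without WT replicate 1 (0.0655), WT replicate 3 (0.0886), KO replicate 2 (0.0601) or KO replicate 4 (0.0782). Neutrophil markers were lower in the same libraries, and with their level as a covariate the PBX, MEIS and HOX list was not called (adjusted p = 0.134, median -0.51). Meis3 (-2.91, SE 0.71) and Hoxb4 (-1.16, SE 0.52) were then about as low as without it (SE 0.27 and 0.20), with larger SE, and Pbx2 stood at -0.42 (SE 0.33).

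B-lineage genes were expressed in both genotypes and moved in both directions. Of 22 pro-B and pre-B markers 4 rose (5 when adjusted over the list alone), 9 fell and 9 did not pass (camera adjusted p = 0.446), with Cd93 at -0.81 and the B-cell factor Ebf1 at 0.61 (370 ± 16.9 to 563 ± 52.5 CPM). This list was called as lower by fry (adjusted p = 0.0229) and with the neutrophil covariate (median -0.39, adjusted p = 0.0326). Of 16 genes of pre-B cell receptor signalling 3 rose, 4 fell and 9 did not pass (adjusted p = 0.762), with Ikzf3, the factor Aiolos, at 1.70 (107 ± 13.4 to 346 ± 37.6 CPM) and Blnk at -0.91. The median of this list was -0.02 while camera's direction was upward, and the median was 0.04 with upper-quartile factors and 0.10 in limma-trend on log2 of CPM plus 1. Of 17 mature B cell markers 3 rose, 5 fell and 9 did not pass (adjusted p = 0.649), with the complement receptor Cr2 at 2.41 and Ltb at -1.24. Without WT replicate 1, KO replicate 3 or KO replicate 4, 3 of these fell. Of 7 plasma cell markers 2 rose, 2 fell (3 when adjusted over the list alone) and 3 did not pass (adjusted p = 0.956), with Xbp1 at -0.83, Derl3 at -1.24 and Prdm1 at 1.54. With any library other than WT replicate 3 left out, 1 rose. Its median of 0.07 and mean of -0.07 differed in sign, and the median was -0.05 without WT replicate 1, -0.07 without WT replicate 3 and -0.02 without KO replicate 4. With the neutrophil covariate the median was -0.80. Of 12 STAT5 target genes 3 rose, 5 fell and 4 did not pass (median -0.11, and 0.0041 in limma-trend on log2 of CPM plus 1; adjusted p = 0.568), with Socs1 at -1.55, Ccnd3 at -1.21 and Pim2 at 1.16, and fry called it as lower (adjusted p = 0.0368).

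Among the remaining lists camera called that of Xist and Y-linked genes. Of 5 pro-survival BCL2 family genes 1 fell and 4 did not pass (adjusted p = 0.762). It was Mcl1 at -0.66, a call lost without KO replicate 2 (adjusted p = 0.0559) or KO replicate 4 (0.0556). In this list 0 fell without KO replicate 2 and 2 without WT replicate 3. Of 9 pro-apoptotic BCL2 family genes 4 fell and 5 did not pass (adjusted p = 0.446), with Bad at -0.82 and Bbc3, which encodes PUMA, at -1.11. Only 2 of the 9 fell without KO replicate 2, and 1 rose without WT replicate 1. Of 9 DNA methylation enzymes 3 rose, 3 fell and 3 did not pass (adjusted p = 0.812), with the methylcytosine dioxygenase Tet1 at -3.16 (22.1 ± 0.698 to 2.47 ± 0.244 CPM), Tet3 at 0.95 and Dnmt3a at -0.60. Its median was 0.17 and its mean -0.17. Of 18 NF-kB target genes 3 rose, 9 fell and 6 did not pass (adjusted p = 0.0953), with Il1b at -3.48 and Bcl3 at -1.61 beside the lower neutrophil markers. This list was called as lower without WT replicate 4 (median -0.85, adjusted p = 0.0261, range 0.00889 to 0.875). The number risen was 1 without WT replicate 4 or KO replicate 3. Fry called as lower this list (adjusted p = 0.0474) and that of pro-apoptotic genes (0.0341). Of 21 nuclear oxidative phosphorylation genes 7 rose, 1 fell and 13 did not pass, with 3 up and 0 down when adjusted over the list alone (adjusted p = 0.287), and Ndufa4 stood at 0.74. Between 2 and 4 of these genes rose without any one library other than WT replicate 3 (2 without WT replicate 4), and 0 fell without any library other than WT replicate 1. Of 18 cholesterol synthesis genes 1 fell, 0 when adjusted over the list alone (adjusted p = 0.964). It was Msmo1 at -0.93, a call lost without KO replicate 2 (0.0619) or KO replicate 3 (0.0666). Without WT replicate 3, 2 cholesterol genes rose, and without WT replicate 4, 3 fell. The median of that list was -0.06 and 0.05 in limma-trend on log2 of CPM plus 1, and camera's direction was upward. It turned downward without WT replicate 4 (median -0.20) and without KO replicate 4 (median -0.17). Of 12 transcripts of the mitochondrial genome 8 fell and 4 did not pass (median -0.64, adjusted p = 0.097), with mt-Co1 at -0.84. That number was 2 without WT replicate 4 or KO replicate 4 and 1 without KO replicate 3. Without WT replicate 1 (adjusted p = 0.0425) and without KO replicate 2 (0.0109) this list was called as lower, as it was with the neutrophil covariate (median -1.10, adjusted p = 0.000322). The mitochondrial share of counts was 2.51, 2.56 and 3.37% in WT and 2.36, 1.73 and 1.73% in KO. In the list of Xist and Y-linked genes all 4 tested rose (camera adjusted p = 0.00306, adjusted p = 0.865 with an estimated correlation; median 7.06 as fitted, 5.42 with genes at 0 in WT at their bound). Xist stood at 883 ± 46.5 CPM in WT and 1158 ± 63.6 CPM in KO. Ddx3y was at least 82.7-fold and Kdm5d at least 22.3-fold higher in KO, against 0 counts over the WT libraries and a floor of 3 counts over the group. For lists with no second count given, the counts were the same when adjusted over the list alone.

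Each genotype's libraries held the same immunoglobulin heavy-chain V segments at high shares. Ighv2-5 (chromosome 12 from 113685482 to 113686045) held 25.7% (95% Clopper-Pearson interval 23.9 to 27.5), 30.3% (28.7 to 32.0) and 34.5% (32.8 to 36.2) of the heavy-chain V counts in KO replicates 2, 3 and 4, and at most 0.120% in any WT library. In WT replicates 1, 3 and 4, Ighv8-7, annotated as a pseudogene (chromosome 12 from 115258136 to 115258432), held 20.5, 29.7 and 24.6%, and at most 0.136% in any KO library. Ighv5-16 led in WT replicate 1 with 20.6% (19.1 to 22.2), and it held 26.6 and 24.2% in WT replicates 3 and 4 and at most 0.911% in KO. Ighv3-4 ranked next in WT, with at least 15.4% in each library. Light-chain shares are of the kappa and lambda V counts together. Igkv3-4 led in the WT libraries with 25.3% (23.6 to 27.0), 65.9% (64.8 to 67.0) and 36.6% (35.1 to 38.2), against at most 0.906% in KO. Igkv4-51 led in KO replicate 2 with 13.1% (12.1 to 14.2), and Igkv14-111 led in KO replicates 3 and 4 with 12.3% (11.4 to 13.3) and 14.5% (13.4 to 15.7). The labels do not say whether the libraries of a genotype came from separate leukaemias, and the tests above measure the spread among these libraries only. If they came from a single leukaemia per genotype, these tests cannot tell genotype from leukaemia.

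**Figure D4:**
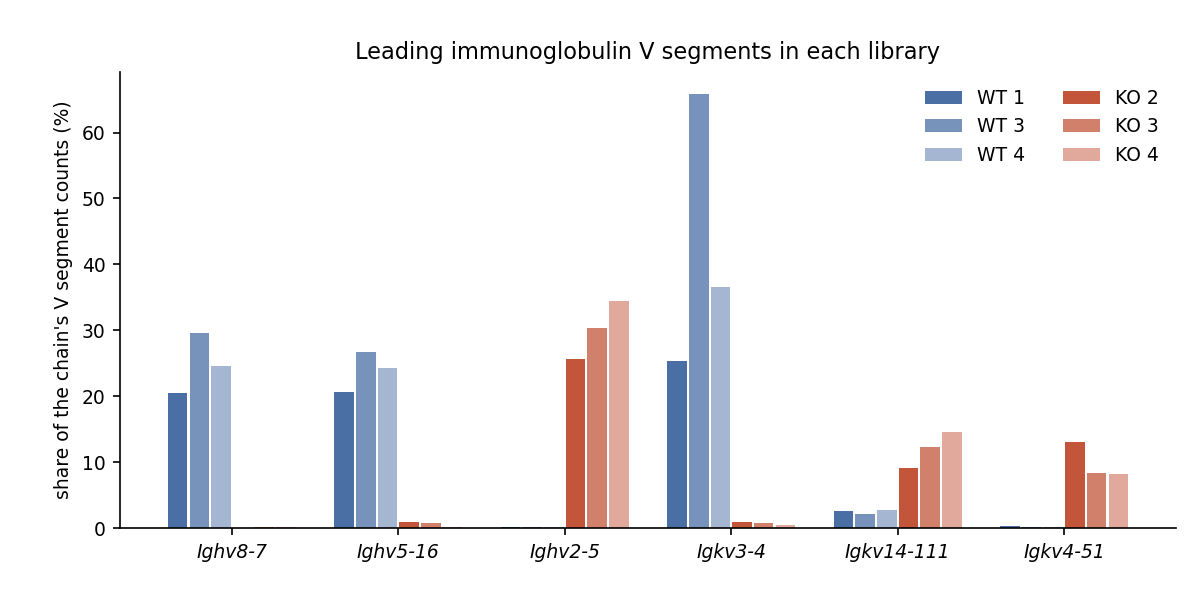
Share of the V segment counts of the chain, in percent, for 6 leading V segments in each of the 6 libraries; bars are single libraries. Ighv2-5 holds 25.7 to 34.5% in KO and at most 0.120% in WT, and Ighv8-7 holds 20.5 to 29.7% in WT and at most 0.136% in KO.

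The authors deposited their own comparison of the same counts, made with DESeq2. It lists 3196 genes with a log2 fold change of at least 1 and an FDR of at most 0.05, 823 higher and 2373 lower in KO. Of these, 2819 were tested here and 2766 were also among the 2915 genes changed at least 2-fold, every shared gene in the same direction, while 377 had too few counts to be tested here. The deposited table gives Pbx3 a log2 fold change of -0.80 (FDR 0.149) and Bcl2 -0.12 (FDR 0.578). With the neutrophil marker level as a covariate, 450 genes were shared.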

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

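The counts recovered from the CPM tables, the neutrophil marker level as a covariate and leaving out chromosomes 12 and 19 were chosen after the data had been seen; the other alternatives were not. Over them the number of genes changed (7599) lay between 5847 and 9811, the number changed at least 2-fold (2915) between 2015 and 3657, and the number shared with the authors' table (2766) between 1970 and 3171, except with the neutrophil covariate, which gave 485, 477 and 450. Genotype took 82.1% of the variance of that covariate, so the fit compares genotypes within what is left, and 482 of the 485 genes were among the 7599. Without each library in turn the number of genes changed ran from 5847 (without WT replicate 4) to 8327 (without WT replicate 3). With limma-trend on log2 of the CPM tables plus 1, which changes the tool, the pseudocount and the scaling together, the log2 fold changes of all genes moved up by a median of 0.113 (0.114 with 0.1 added in place of 1), and 57.2% of the 8094 genes called were higher in KO, against 45.6%. Upper-quartile factors, which change the scaling alone, gave 4011 genes higher and 3802 lower, so the majority depends on the scaling. Bcl2 stayed on the same side of the threshold and of 0 in all 23 alternatives. Pbx3 passed as lower in limma-voom with quality weights (-1.04) and without WT replicate 3, with values from -1.06 to -0.65 over the left-out libraries, and turned to 0.062 with the neutrophil covariate. With an estimated correlation 0 of the 38 lists were called, against 11 to 19 in the other settings. Genes with a seed match passed in fry only (-0.074), and lay between -0.09 and -0.05 over the left-out libraries. The numbers 3 and 4 stand in both genotypes. Libraries with the same number had correlations of 0.027 and 0.162, within the range of the others (-0.347 to 0.335). With so few such pairs this can neither show nor rule out that the numbers pair the samples, and the main fit did not pair them. With the replicate block 6767 genes and 15 lists were called, 12 of the 16 and 3 others. The other numbers each stand in 1 genotype, so that fit estimated the genotype difference from replicates 3 and 4 alone.

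With the neutrophil covariate the direction turned, with no adjusted p below 0.05, for Mitf (0.80), Pdcd4 (-0.76), Fbxw7 (-0.26), Bcl2a1d (1.07), Rad52 (0.061), Aurka (0.063), Irf4 (-0.028), Nkg7 (0.45), Gzma (0.66), Retnlg (0.087), Slc4a1 (0.91), Hbb-bt (0.92), Alas2 (1.14), Siglech (1.35), Cd34 (0.22) and Pecam1 (-0.17), and for camera's test of the lists for pre-B cell receptor signalling (median -0.21), cholesterol synthesis (-0.16), neutrophils (0.10), dendritic cells (0.65) and stroma (-0.10). Camera's direction held but the median turned for the plasma cell (0.07 to -0.80), erythroid (-0.04 to 1.12) and mature B (-0.54 to 0.12) lists. The same was true of the oxidative phosphorylation (0.06 to -0.0031) and reported target (-0.02 to 0.02) lists. The replicate block turned Fbxw7 (-0.045), Bcl2l1 (-0.031), Slc4a1 (0.71), Hbb-bt (1.19), Alas2 (1.51) and the test of the mature B list (median 0.15). Limma-voom turned Slc4a1 (0.15), Hbb-bt (0.35) and Alas2 (0.60), and with quality weights Bcl2l1 (-0.059), Hbb-bt (0.69) and Alas2 (0.89). The CPM tables, under either name, gave Hbb-bt 0.20 and Alas2 0.30, and with 0.1 added Slc4a1 0.0068, Hbb-bt 0.33 and Alas2 0.55. Cholesterol synthesis also turned without chromosomes 12 and 19 (-0.10) and in fry (-0.064). Without WT replicate 1 the direction turned for Fbxw7 (-0.0023), Bcl2l1 (-0.015), Slc4a1, Hbb-bt and Alas2; over the left-out libraries these ran from -0.0023 to 0.17, -0.015 to 0.13, -1.45 to 0.60, -0.91 to 1.18 and -0.84 to 1.49. Hbb-bt and Alas2 passed as higher there (adjusted p = 0.00986 and 0.00874) and with the block (0.000583 and 0.000358). The block fit takes no genotype difference from WT replicate 1 either, so these 2 results are not separate evidence. The list median ran from -0.20 to 0.085 for cholesterol synthesis and from -0.23 to 0.14 for plasma cells. The cause was not tested for any of these changes. For the 150 named genes that passed, 198 calls were lost over all alternatives, 101 of them with the neutrophil covariate. That covariate is the mean of the neutrophil markers, so the neutrophil list itself cannot be judged with it. A gene that did not pass is not shown to be unchanged.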

Other observations

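The chromosome tests, the clone, neutrophil and Y-linked tests and the neutrophil covariate were chosen after the results had been seen; the tests of GC content, depth and other splits were written down before theirs were.

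Genes of chromosomes 12 and 19 were lower in KO as a whole. Over genes with a mean of at least 8 CPM, the median log2 fold change was -0.44 on chromosome 12 (362 genes, interquartile range -0.74 to -0.13, camera adjusted p = 4.27e-05, adjusted p = 0.0449 with an estimated correlation) and -0.50 on chromosome 19 (368 genes, -0.81 to -0.20, camera adjusted p = 4.43e-10, adjusted p = 0.0449 with an estimated correlation). On these chromosomes 82.6% and 88.6% of genes were lower in KO, while the medians of the other 18 lay between 0.01 and 0.13. In WT, a single extra chromosome beside a pair would give -0.58 if expression followed copy number. Copy number was not measured, and these values do not tell a gain in WT from a loss in KO. Dntt (-7.94), Blnk (-0.91) and Ifit1 (-3.83) on chromosome 19 are among the named genes that fell. So are Smoc1 (-7.39), Dnmt3a (-0.60) and Mycn (-0.91) on chromosome 12. Dntt, Ifit1 and Smoc1 fell by far more than the median of their chromosome. Around Cdkn2a on chromosome 4, 3 non-coding transcripts (Gm12606, Gm12609 and Gm12610) had 0 counts in all WT libraries and were at least 16.8, 39.6 and 33.6-fold higher in KO, Mtap rose by 0.96 (adjusted p = 0.00055), Focad and Klhl9 did not pass (0.24 and -0.17), and Hacd4 fell by 3.45. These genes were named after their values were seen. Whether this stretch was lost in WT or switched on in KO was not tested.

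Libraries of a genotype held the same heavy-chain V segments at high shares, and the genotypes differed on chromosomes 12 and 19. A candidate explanation is one leukaemic clone per genotype, from the same shares that prompted it: the leading heavy-chain V segment of each group held at least 20.5% in its own libraries and at most 0.136% in the others. WT held 3 such segments in each library (Ighv3-4 at 15.4% or more, beside Ighv8-7 and Ighv5-16). In each KO library Igkv14-111 (9.03 to 14.5%) and Igkv4-51 (8.27 to 13.1%) were the 2 leading light-chain segments, with at most 2.77% and 0.347% in WT. This recurrence goes with a shared origin of a genotype's libraries. The shares do not tell 1 clone from several, so the explanation of one clone per genotype stays open. GC content is excluded as the cause of the shift of chromosomes 12 and 19, since after medians of 20 GC bins were removed they stood at -0.46 (-0.51 to -0.37) and -0.53 (-0.57 to -0.48). Lower depth of the WT libraries is excluded as the cause of the number of calls, since 7355 genes were called with all libraries thinned to the smallest total, 7160 of them shared with the 7599. The effect of miR-182 stays open as an untested biological explanation.

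Neutrophil markers were lower in KO, although the sort took B220 positive cells. A candidate source is more neutrophils among the sorted cells of the WT mice: within genotypes the 17 markers rose and fell together with a mean pairwise correlation of 0.665, above the highest of 10000 lists matched on expression (0.541), with S100a8, S100a9 and Lcn2 among the list. Markers that are regulated together would also move together, so the correlation cannot decide for this source. A lower share of leukaemia cells in WT is not excluded. An equal rise of every other cell type is disfavoured, since the erythroid median lay 2.91 above the neutrophil median, beyond the interquartile ranges of 0.542 and 1.07. That gap rests on the erythroid list of 7 tested markers, whose mean log2 CPM was 4.86, 2.02 and 3.04 in WT replicates 1, 3 and 4. Medians of the other non-B lists lay between -2.49 (mast cells) and -0.59 (stroma). An effect of genotype on neutrophil genes stays open, and with 82.1% of the marker level's variance taken by genotype it could not be separated from the other lists.

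Y-linked transcripts were found in KO libraries, with 125, 233 and 419 counts over 4 genes against 1, 1 and 0 in WT, beside Xist in all 6. Reads of X-linked homologues are excluded as the source, since WT held 2 Y-linked counts where the KO ratio would give 608. Cells that are all male are excluded too, since the lowest Xist level of a KO library was 1.24 times the WT mean. A mixture of male and female cells, as from a donor and a host of different sex, may be the source but was not tested, and the labels give no sex.

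With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 cannot be reached. Every split but the real one mixes the genotypes in both groups. Part of the genotype difference then stays in the contrast and the rest adds to the spread, so these splits do not measure chance. As many genes changed in 1 of the 10 splits, the real one (7599, highest other 0), as many changed at least 2-fold in 1 (2915, highest other 0), and as large a difference for seed matches in 1 (0.0744, highest other 0.0629). As many lists were called in 6 of the 10 (16, highest other 20).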
